A study of Mus musculus with 15 samples.

How the data were processed

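RNA from mouse MC3T3 cells (clone 1b, an osteoblast precursor line derived from mouse calvaria) was measured on 15 single-colour oligonucleotide arrays. The labels gave 5 groups of 3 arrays each: growth medium at day 0, beta-glycerol phosphate (GP) at days 1 and 3, and GP with ascorbic acid and bone morphogenetic protein 2 (BMP-2) at days 1 and 3. Each array also carried a preparation number, 1 to 3, which is called the replicate here. Nothing in the labels says whether the preparations were separate cultures, so p-values measure the spread between these samples, which may be technical.

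The deposited values were linear intensities per probe set for 12488 probe sets on each array. The software that made them was not given in the sources used here, and no detection calls were used. The mean of each array's values between its 2nd and 98th percentiles was 150.0 on every array, so the arrays had been scaled to a common trimmed mean before they were deposited. Array medians ran from 38.4 to 50.6, a ratio of 1.32, which was under the limit of 1.5 set for keeping that scaling. The 66 control probe sets were left out of the tests. Values under 2.8, the 10th percentile of all values, were set to 2.8, and log2 values were taken. Probe sets with a mean signal under 22.3, the 40th percentile, were then left out, which left 7453 tested probe sets. As these are arrays, their number limits the precision.

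Of the 12422 probe sets other than controls, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none. Names were taken only from probe sets with 1 symbol, which were 6743 of those tested and stood for 5643 genes. The Entrez identifiers of 10839 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used only for names, and 0 symbols changed. Where a gene had several probe sets, the one with the highest mean signal was used. Disagreement between probe sets of a gene is given where it concerned a named gene. The probe sets used for Srm, Gadd45b, Kifc1, Aldoa, H2-K1, H2-D1, Nid2, Nqo1, Plk1 and Egfr carry manufacturer's suffixes for shared or similar sequences or for relaxed probe design, so signal from another transcript was not excluded for them.

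Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend). All 15 arrays entered a single fit with 1 coefficient per group and 10 residual degrees of freedom, so the groups shared an estimate of the spread. P-values were adjusted with the Benjamini-Hochberg method and called at 0.05. Contrasts were treated against GP cultures at day 1 and at day 3, the difference between those effects (the interaction), GP day 1 against day 0, GP day 3 against day 1, GP day 3 against day 0, and treated day 3 against day 1. Ascorbic acid and BMP-2 were always added together, so their effects cannot be separated, and medium and time changed together between day 0 and GP day 1. Errors of log2 fold changes are standard errors from the fit, and group intensities are means ± SD.

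The 25 gene lists were drawn up before the data were examined, as were the named-gene rule, the contrasts, the main settings and all alternatives except those said to be added. They covered osteoblast genes, BMP and TGF-beta feedback, collagen maturation, other extracellular matrix, matrix proteases and inhibitors, cell cycle, cell cycle arrest and p53 targets, smooth muscle and contractile genes, the Wnt pathway, osteoclast regulation and paracrine factors, interferon response, chemokines and inflammation, immediate early and serum response, cholesterol synthesis, endoplasmic reticulum chaperones and stress, hypoxia and glycolysis, oxidative stress and detoxification, and phosphate and mineral handling. Markers of other cell types formed the lists adipocyte, chondrocyte, skeletal muscle, macrophage and osteoclast, endothelial, epithelial, and neural and glial. Lists were tested with camera in limma at its preset correlation of 0.01, with 1 probe set per gene and Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. That correlation was estimated from the fit without the replicate number, so differences between replicate numbers can enter it. Each list also has a count of genes adjusted over the list alone.

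The named genes were, for treated against GP cultures at each day, the 12 largest increases and the 12 largest decreases among genes past the threshold whose values did not overlap between the groups. For the interaction and 3 of the time contrasts the rule took 5 each way. GP day 3 against day 0 had only counts and lists. A fixed set of bone and BMP genes was also named where tested, with others of that set not analysed here, and up to 4 genes with the smallest p per list. Genes outside this rule are said to have been chosen after their values were seen.

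The replicate numbers were checked for pairing from the deviations of each array from its group mean. Arrays with the same number correlated at 0.19 to 0.70 and arrays with different numbers at -0.57 to 0.26. All 15 arrays correlated best, on average, with arrays of their own number. The pairing comes from the preparation number in the labels, and a fit with that number as a block, with 8 residual degrees of freedom, was run as an alternative.

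Other alternatives were floors at the 2nd and 25th percentiles, no signal filter, a filter at the 60th percentile, quantile normalization, median scaling, eBayes without a mean trend or with robust estimation, array weights, fits of only the groups compared, a minimum fold of 1.5, and leaving out each array or preparation. A floor at the 50th percentile, 45.6, and the cell cycle list without 1 array were added after the data were seen. The tests were checked on simulated data with 7453 probe sets, of which 200 were changed by 0.5, 1 or 2 on the log2 scale. Noise was drawn independently for each probe set and added to the real differences between replicate numbers, so the shares in the real data may differ. For treated against GP at day 1, 28.4% of changes of 1 on the log2 scale and 72.7% of changes of 2 were recovered. At day 3 these shares were 37.3% and 80.3%. With the block, 68.7% and 90.9% were recovered at day 1, and 65.7% and 90.9% at day 3. Of changes of 0.5, only 4.48% at day 1 and 1.49% at day 3 were recovered, and 16.4% and 19.4% with the block. False calls were 0 of 70 at day 1 and 1 of 80 at day 3, and with the block 8 of 125 (6.4%) and 7 of 124 (5.65%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.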

Results

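Gene expression was measured in MC3T3 cells, a mouse calvarial line whose cells can become osteoblasts, under conditions used to drive that differentiation. The 15 arrays formed 5 groups of 3: growth medium at day 0, GP alone at days 1 and 3, and GP with ascorbic acid and BMP-2 at days 1 and 3. GP is a phosphate source for mineral, ascorbic acid is a cofactor of collagen hydroxylation and BMP-2 is a bone-inducing growth factor. Cultures given all 3 additions are called treated. The number of arrays limits the precision. Across arrays, the first principal component held 32.7% of the variance and set the replicate 3 arrays, at -25.3 to -39.7, apart from the others, at 1.55 to 25.6. The replicate 3 arrays also had more values at the floor, 12.9% ± 0.83 (SD, n = 5), than replicates 1 and 2, at 9.08% ± 0.72 and 8.04% ± 0.72. The GP day 3 replicate 3 array had an actin 3' to 5' signal ratio of 2.11, a sign of RNA quality, where the other arrays had 1.00 to 1.34.

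The first comparison asked what ascorbic acid and BMP-2 changed after 1 day. Smad6, an inhibitory Smad of the BMP pathway, rose from 229 ± 45.5 to 745 ± 52.4 intensity units (SD, n = 3 arrays per group), a log2 fold change of 1.72 ± 0.29 (SE). The homeobox genes Dlx1 and Dlx2 rose by 1.54 ± 0.33 and 1.41 ± 0.23, and Zfp703, which encodes a zinc finger transcriptional regulator, rose by 1.67 ± 0.19. The largest decreases were in Enpep, a glutamyl aminopeptidase, at -3.51 ± 0.57, and Ifi47, an interferon-inducible GTPase, at -3.36 ± 0.61, for which 1 treated value lay at the floor. Crabp2, a carrier of retinoic acid, fell by 2.40 ± 0.47, and Aox1, an aldehyde oxidase, fell by 2.40 ± 0.28. In limma with Benjamini-Hochberg adjustment, 69 of 7453 probe sets passed the threshold at day 1, 22 higher and 47 lower, and the adjusted p was 0.0158 for Smad6, 0.0477 for Dlx1, 0.0107 for Dlx2, 0.00117 for Zfp703 and Aox1, 0.0107 for Enpep, 0.0191 for Ifi47 and 0.0287 for Crabp2. With the replicate number as a block, 372 passed, 154 higher and 218 lower, including all 69. This blocked count was 212, 105 and 172 without GP day 1 replicates 1, 2 and 3 and 232, 168 and 243 without treated replicates 1, 2 and 3. Treated means of Enpep (21.1 ± 13.8), Aox1 (19.2 ± 4.80), Ifi47 (6.23 ± 6.04) and Cmbl (8.97 ± 3.38) lay under the signal filter of 22.3, so the sizes of their changes are uncertain. With a floor of 45.6, added after the data were seen, the changes were -2.21, -1.12, -0.35 and -0.01, and only Aox1 among these 4 passed (adjusted p = 0.0615, 0.0423, 0.578 and 1).

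Other named increases at day 1 were Gadd45b, a stress-inducible growth regulator, at 1.41 ± 0.25, Srm, spermidine synthase, at 1.32 ± 0.21, and Nhp2, a component of ribonucleoproteins that modify RNA, at 1.06 ± 0.18. Klf10, a TGF-beta-inducible transcription factor, rose by 1.05 ± 0.20. Plpbp, Sec13, Dcaf13 and Dlst rose by 0.93, 0.90, 0.88 and 0.84, with SEs of 0.20, 0.15, 0.15 and 0.13. Named decreases were Synpo, an actin-associated protein, at -2.11 ± 0.38, Cmbl at -2.07 ± 0.45, Ogn, a small proteoglycan of bone matrix, at -1.66 ± 0.35, Xrcc5, a subunit of the Ku DNA repair complex, at -1.44 ± 0.29, and Dbndd2 at -1.37 ± 0.27. Ddit4, a stress-induced inhibitor of growth signalling, Pdk1, a kinase that restrains pyruvate oxidation, and P4ha1, a subunit of collagen prolyl 4-hydroxylase, fell by 1.82 ± 0.28, 1.72 ± 0.30 and 1.57 ± 0.22. Without GP day 1 replicates 1, 2 and 3, the day 1 count was 15, 13 and 37, and without treated replicates 1, 2 and 3 it was 37, 16 and 43. In the same fits 5, 5 and 14 and then 15, 6 and 19 of the 24 named genes stayed past the threshold, and 3 of them, Aox1, P4ha1 and Zfp703, did so in all 6. The calls of Crabp2, Plpbp, Enpep, Ifi47, Ogn, Cmbl, Dlx1, Xrcc5, Dbndd2, Dcaf13, Synpo and Nhp2 were lost in at least 1 of the fits with the added floor, no signal filter, quantile normalization, median scaling or no mean trend. Dbndd2 changed by -0.81 with the added floor. In a fit of only the day 1 groups, Smad6 and Srm passed and the other 22 named genes did not.

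Several bone and BMP genes had large differences at day 1 that did not pass the threshold without the block. Alpl, tissue-nonspecific alkaline phosphatase and an early osteoblast marker, was at 109 ± 73.7 in treated and 20.2 ± 3.21 in GP cultures, a log2 difference of 2.24 ± 0.50 (limma adjusted p = 0.0519, and 0.0212 with the block). Its GP mean lay under the signal filter of 22.3, so the size of this difference is uncertain, and with the added floor it was 1.06 (adjusted p = 0.284). Id3, an inhibitor of basic helix-loop-helix factors, differed by 1.79 ± 0.41 (adjusted p = 0.0580, and 0.00440 with the block). The BMP feedback gene Smad7 differed by 1.11 ± 0.26 (0.0616, and 0.00858 with the block), Dlx5 by 0.87 ± 0.23 (0.0973, and 0.0250 with the block) and Msx2 by 1.29 ± 0.38 (0.159, and 0.00857 with the block). Id2, at 2.24 ± 0.61, and Id1, at 1.55 ± 0.55, passed in neither of these fits. With quantile normalization Alpl (adjusted p = 0.0441) and Smad7 (0.0478) passed. Alpl also passed with the floor at the 25th percentile (0.0499) and robust estimation (0.0492), Id3 and Smad7 with median scaling (0.0436 and 0.0332) and with the filter at the 60th percentile (0.0462 and 0.0486), and Id2 in a fit of only the day 1 groups (0.0395). With array weights Alpl (0.0120), Id3 (0.00698), Id2 (0.0101), Smad7 (0.0323) and Dlx5 (0.0159) did. Nog, a BMP antagonist, differed by 0.10 ± 0.39, and Col1a1, the main bone collagen gene, by -0.05 ± 0.17. The sign of Col1a1 turned to 0.05 with quantile normalization, and its second probe set had the opposite sign.

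**Figure D1:**
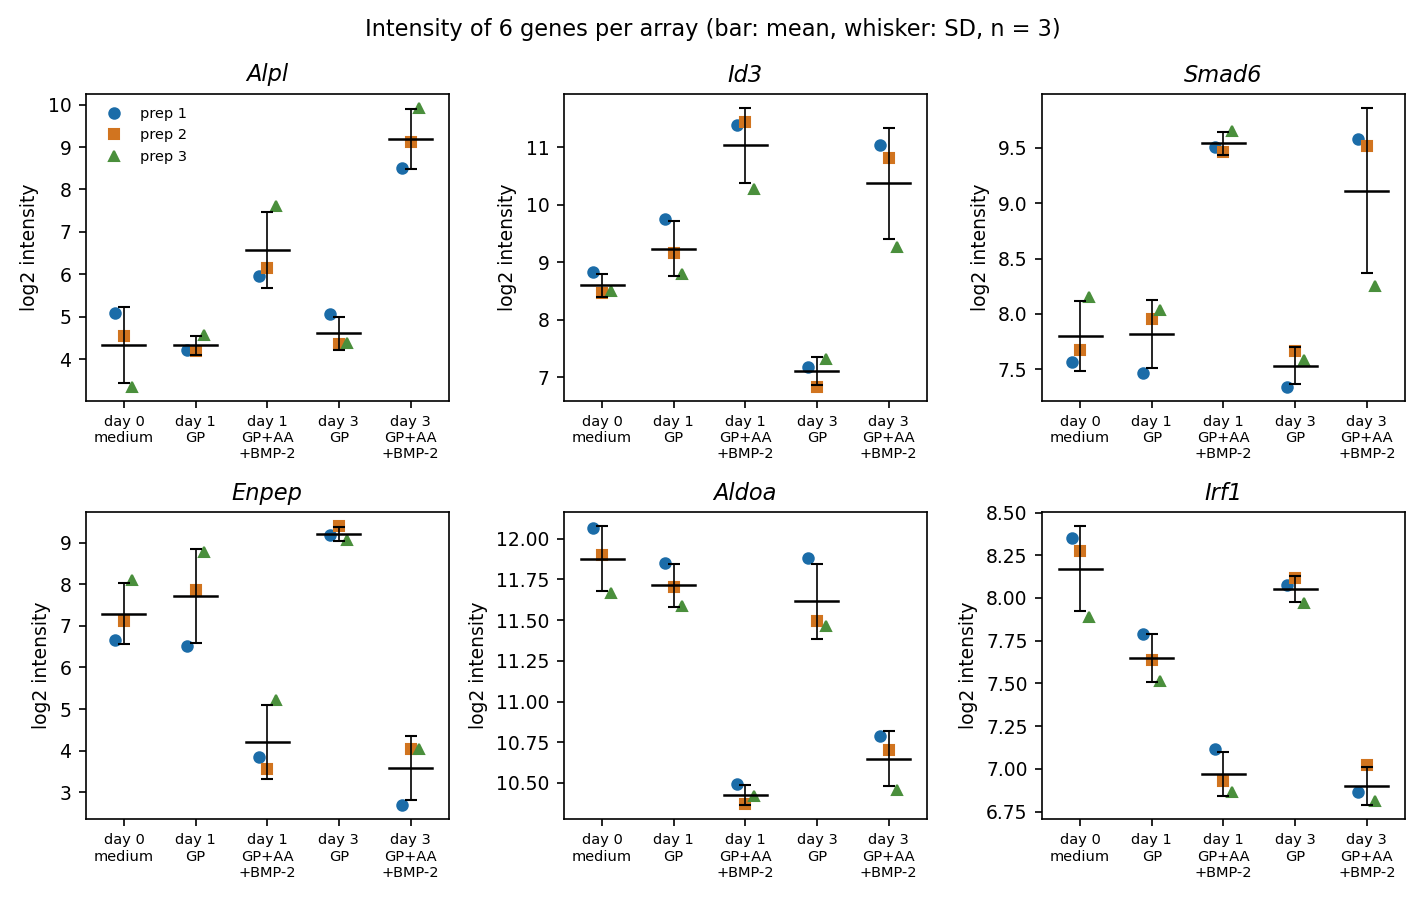
Log2 intensity (y axis) of Alpl, Id3, Smad6, Enpep, Aldoa and Irf1 on each array, by group (x axis), with points shaped and coloured by prep number, bars at the mean and whiskers of 1 SD (n = 3). At day 3, Alpl, Id3 and Smad6 lay higher in each treated array than in each GP array, and Enpep, Aldoa and Irf1 lay lower.

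As groups at day 1, genes of hypoxia and glycolysis had the smallest p. Of 19 tested genes 5 fell and 0 rose: Ddit4, Pdk1, the glycolytic enzymes Aldoa (-1.29 ± 0.15) and Pgk1 (-0.97), and Egln1, an oxygen-sensing prolyl hydroxylase (-1.19 ± 0.24). Adjusted over the list alone 14 fell, and with the block 8 fell. The Egln1 call was lost with no signal filter (0.0520), median scaling (0.128) and no mean trend (0.0524). In a fit of only the day 1 groups, 1 probe set in all was lower and past the threshold. The median log2 fold change was -0.66, and camera gave an adjusted p of 2.5e-13 (adjusted p = 0.0554 with an estimated correlation). In the interferon response list 2 of 19 fell, Ifi47 and H2-K1, a class I histocompatibility gene (-1.01 ± 0.16), with 8 lower adjusted over the list alone and 1 higher and 8 lower with the block. Another probe set of H2-K1 had the opposite sign at day 1, and the H2-K1 call was lost in a fit of only the day 1 groups (0.0852). The list median was -0.57 and its camera adjusted p 3.6e-08 (adjusted p = 0.151 with an estimated correlation). Of 25 oxidative stress and detoxification genes 0 passed over all genes, 1 higher and 5 lower passed adjusted over the list alone, and 1 higher and 6 lower with the block (median -0.27, camera adjusted p = 0.00752). That list call was lost with an estimated correlation (adjusted p = 0.178 with an estimated correlation).

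Higher lists at day 1 had few genes past the threshold. Among 25 BMP and TGF-beta feedback genes Smad6 rose, 5 rose and 1 fell adjusted over the list alone, and 6 rose and 1 fell with the block (median 0.27, camera adjusted p = 0.000345, and adjusted p = 0.178 with an estimated correlation). Of 51 cell cycle genes 0 passed, 3 rose adjusted over the list alone and 6 with the block (median 0.28, camera adjusted p = 7.0e-08, and adjusted p = 0.345 with an estimated correlation). Of 16 cholesterol synthesis genes 0 passed, also adjusted over the list alone, and 2 rose with the block (median 0.52, camera adjusted p = 0.000116, and adjusted p = 0.345 with an estimated correlation). Of 13 osteoblast genes 0 passed, and 3 rose adjusted over the list alone and with the block (median 0.45, camera adjusted p = 0.0261, and adjusted p = 0.345 with an estimated correlation). The osteoblast call was lost without replicate 2 (median 0.18, adjusted p = 0.176) and with no signal filter (median 0.28, 0.0952), and without replicate 3 the cell cycle median was 0.13.

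After 3 days of treatment, Alpl stood at 630 ± 310 intensity units against 24.97 ± 7.31 in GP cultures (SD, n = 3), a log2 fold change of 4.58 ± 0.50 (SE). The BMP target genes Id3 and Id2 rose by 3.26 ± 0.41 and 3.15 ± 0.61, and Smad6 rose by 1.58 ± 0.29. Ccn2, a matricellular growth factor, rose by 3.09 ± 0.64, Tgfb1, transforming growth factor beta 1, by 2.36 ± 0.33, Tnc, the matrix protein tenascin C, by 2.35 ± 0.45, and Tnfrsf11b, osteoprotegerin, a decoy receptor that blocks osteoclast formation, by 2.00 ± 0.31. Tnnc1, troponin C of slow and cardiac muscle, was at 3.6 ± 1.4 against 255 ± 127, with 1 treated value at the floor, and Enpep was at 13.1 ± 5.72 against 595 ± 71.6, a log2 fold change of -5.62 ± 0.57. The basement membrane genes Col4a1 and Nid2 fell by 2.24 ± 0.28 and 2.29 ± 0.36. In limma with Benjamini-Hochberg adjustment 306 of 7453 probe sets passed, 151 higher and 155 lower, with adjusted p = 0.000406 for Alpl, 0.00114 for Id3, 0.0107 for Id2, 0.000206 for Tnnc1 and 0.000226 for Enpep. Treated means of Tnnc1 and Enpep lay under the signal filter of 22.3, and each GP value of Alpl at day 3 lay under the added floor of 45.6, so the sizes of these changes are uncertain. With the added floor they were -2.37, -3.70 and 3.67 and still passed (adjusted p = 0.00175, 0.00270 and 0.00138). In a fit of only the day 3 groups Smad6 and Id2 did not pass (0.0863 and 0.0873). With the block 1031 passed, 510 higher and 521 lower, including all 306, and 625 and 610 without GP day 3 replicates 1 and 2.

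The remaining named increases at day 3 were Amacr, an enzyme of branched fatty acid metabolism, at 2.76 ± 0.73, the mitotic kinesin Kifc1 at 2.45 ± 0.58, Gadd45g at 2.13 ± 0.42, Pkdcc at 1.79 ± 0.43 and the mitotic kinase Ttk at 1.74 ± 0.31. Crabp2 and Cmbl fell by 2.89 ± 0.47 and 3.38 ± 0.45. Runx1t1, a transcriptional corepressor, fell by 2.59 ± 0.51, Fmo1, a monooxygenase, by 2.58 ± 0.48, and Id4 by 2.49 ± 0.31. Ackr3, an atypical chemokine receptor, fell by 2.38 ± 0.32, and Serpinb9, a granzyme B inhibitor, and Aoc3, an amine oxidase, both fell by 2.24, with SEs of 0.30 and 0.37. Dlx5 differed by 0.84 ± 0.23 (adjusted p = 0.0547, and 0.0140 with the block) and Msx2 by 1.06 ± 0.38 (0.151, and 0.0107 with the block). Id1 differed by 1.27 ± 0.55, Col1a1 by 0.28 ± 0.17, Smad7 by -0.02 ± 0.26, which was 0.03 after median scaling, and Nog by 0.01 ± 0.39, and none of these 4 passed. With array weights Id1, at 2.03 (adjusted p = 0.0154), Msx2 (0.0409) and Dlx5 (0.00450) passed, and Dlx5 did with the filter at the 60th percentile (0.0435). Without GP day 3 replicates 1 and 2 the day 3 count was 134 and 119, without treated replicates 1, 2 and 3 it was 171, 174 and 192, and without GP day 3 replicate 3, the array with the high actin ratio, it was 333. Treated means of Fmo1, Runx1t1 and Cmbl also lay under the signal filter, and with the added floor their changes were -0.67, -0.35 and -1.23, of which only the last passed. The calls of Fmo1, Runx1t1, Ccn2, Kifc1, Amacr and Pkdcc were lost in at least 1 of the fits with the added floor, no signal filter, quantile normalization, median scaling or no mean trend, and those of Gadd45g, Aoc3 and Ttk in a fit of only the day 3 groups (0.0863, 0.0721 and 0.0652), where Fmo1, Runx1t1, Kifc1 and Amacr were lost too. Amacr changed by 1.56 with the added floor. In the fits without 1 array 16, 17, 21, 20, 21 and 24 of the 24 named genes stayed past the threshold, and 15 did so in all 6. Without all arrays of replicate 1, 2 or 3 the day 3 count was 20, 2 and 503. In those fits limma had 735, 752 and 1566 probe sets at an unadjusted p under 0.05, where chance gives 373.

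Cell cycle genes made up the broadest group at day 3. Of 51 tested, 19 rose and 0 fell, 43 rose adjusted over the list alone and 41 with the block. Examples were Tacc3, a spindle protein, at 1.59 ± 0.25, the mitotic kinases Aurkb at 1.32 ± 0.16 and Plk1 at 1.29 ± 0.17, and the kinesin Kif2c at 1.44 ± 0.21. Tacc3 had a GP mean of 25.2, and with the added floor its change was 0.70 (adjusted p = 0.0389), while in a fit of only the day 3 groups it did not pass (0.0863). The list median was 0.85, and camera gave an adjusted p of 2.6e-27 (adjusted p = 0.114 with an estimated correlation). GP day 3 replicate 3, with its actin ratio of 2.11, belongs to the lower side of this comparison, and without that array, a fit added after the data were seen, 22 genes of the list rose and its median was 1.03.

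Of 13 osteoblast genes 2 rose at day 3, Alpl and Tnfrsf11b, and Cdh11, osteoblast cadherin, fell by 1.24 ± 0.17. Adjusted over the list alone 4 rose and 1 fell, and with the block 6 rose and 1 fell (median 0.44, camera adjusted p = 0.00323, and adjusted p = 0.196 with an estimated correlation). The osteoblast median was 0.18 without replicate 1 and 0.77 without replicate 3. Within replicates 1, 2 and 3 the median difference of that list at day 3 was 0.96, 0.57 and 0.08. A probe set of Pth1r, a gene of the osteoblast list, was left out by the signal filter. With no filter it rose by 4.56 ± 1.01 at day 3, a size made uncertain by low GP signal. Of 25 BMP and TGF-beta feedback genes Id2, Id3, Smad6 and Tgfb1 rose and Id4 fell, with 6 higher and 1 lower adjusted over the list alone and 7 higher and 1 lower with the block. The test of that list did not pass (median 0.34, camera adjusted p = 0.0559), while it did with quantile normalization (0.0451) and without replicate 3 (0.000262). Its median difference at day 3 was 0.37 and 0.43 in replicates 1 and 2 but -0.13 in replicate 3. Of 34 other extracellular matrix genes 2 rose, Tnc and Col3a1 (1.27), and 6 fell, among them Col4a1, Nid2, Col4a2 (-1.32) and the matrix glycoprotein gene Fbln2 (-1.62 ± 0.16). Adjusted over the list alone 4 rose and 8 fell, with the block 8 rose and 11 fell, and the test did not pass (median -0.12, camera adjusted p = 0.0742), except without replicate 1 (0.0147) or replicate 2 (0.0449).

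The lists that were lower at day 1 were lower again at day 3. In hypoxia and glycolysis 6 of 19 fell: Bnip3, a mitochondrial autophagy receptor (-1.74), Pdk1 (-1.68 ± 0.30), Egln1 (-1.04 ± 0.24), Aldoa (-0.97 ± 0.15), Ndrg1 (-0.87 ± 0.19) and Pgk1 (-0.87). With median scaling Egln1 (0.105) and Ndrg1 (0.0571) did not pass, and in a fit of only the day 3 groups neither they (0.0696 and 0.111) nor Pdk1 (0.0552) did. Adjusted over the list alone 12 fell and with the block 10 (median -0.62, camera adjusted p = 1.2e-08, and adjusted p = 0.114 with an estimated correlation). In the interferon response list 5 of 19 fell, the immunoproteasome gene Psmb8 (-1.45 ± 0.28), the GTPase gene Irgm2 (-1.26 ± 0.30), H2-K1 (-1.16 ± 0.16), H2-D1 (-1.01) and the transcription factor gene Irf1 (-1.16 ± 0.15), with 10 lower adjusted over the list alone and 1 higher and 11 lower with the block. With the added floor Psmb8 changed by -0.94, Irgm2 did not pass with no signal filter (0.0617), and neither passed in a fit of only the day 3 groups (0.0873 and 0.108). The list's median was -0.97, and -0.60 with no signal filter, and its camera adjusted p 1.0e-06 (adjusted p = 0.179 with an estimated correlation). Of 25 oxidative stress and detoxification genes 3 fell, Aldh3a1 (-1.73 ± 0.26), the quinone reductase gene Nqo1 (-1.48 ± 0.29) and Cyp1b1 (-1.37 ± 0.23), with 3 adjusted over the list alone and 5 with the block (Cyp1b1 not in a fit of only the day 3 groups, 0.0726; median -0.31, and -0.20 without replicate 1, camera adjusted p = 0.0162, and adjusted p = 0.198 with an estimated correlation).

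**Figure D2:**
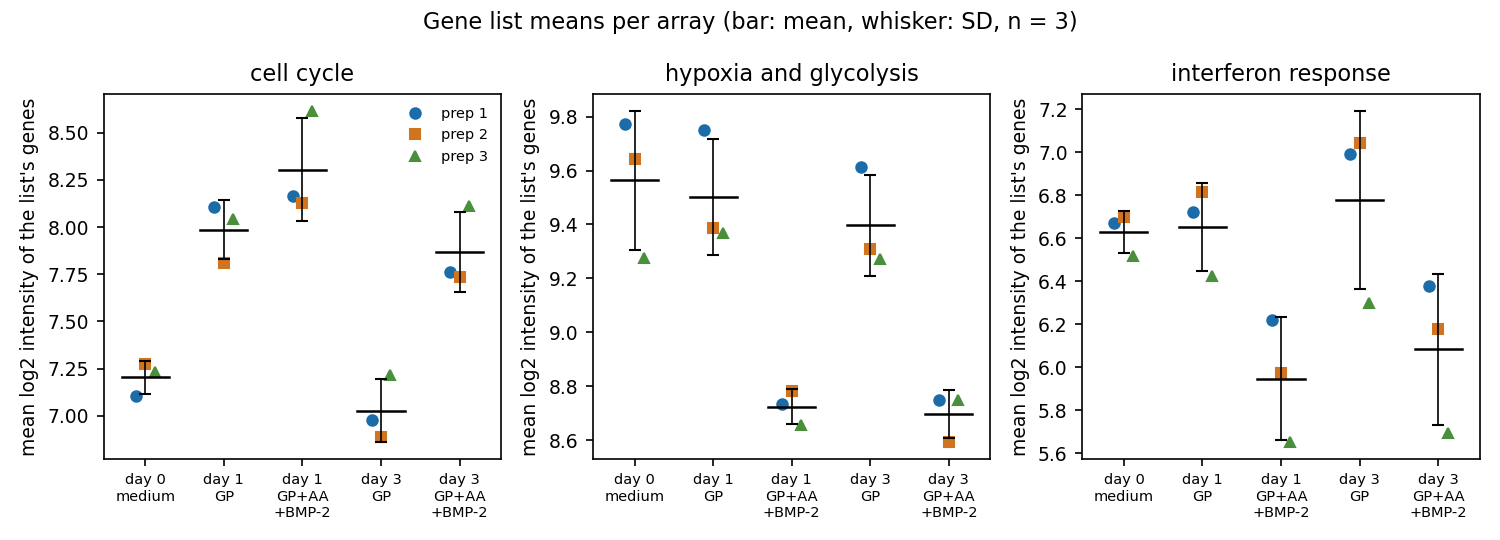
Mean log2 intensity (y axis) of the genes of 3 lists on each array, by group (x axis), with points shaped and coloured by prep number, bars at the mean and whiskers of 1 SD (n = 3). The cell cycle list averaged 7.03 in GP and 7.87 in treated cultures at day 3, the hypoxia and glycolysis list 9.40 and 8.70, and the interferon response list 6.78 and 6.08.

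Cholesterol synthesis was higher at day 3, with Fdps, farnesyl diphosphate synthase, the member that rose (1.28 ± 0.32) among 16. That call was lost with the added floor (adjusted p = 0.0624), no signal filter (0.0828) and no mean trend (0.0582). The same number, 1, passed adjusted over the list alone and 2 with the block (median 0.61, camera adjusted p = 7.0e-05, and adjusted p = 0.294 with an estimated correlation). The osteoclast regulation and paracrine list was lower on balance, although 2 of 19 rose, Tnfrsf11b and Pdgfa, a platelet-derived growth factor chain (1.26 ± 0.26), and 1 fell, the growth factor receptor gene Egfr (-2.16 ± 0.51), which did not pass with the added floor (-0.95, adjusted p = 0.0622), no signal filter (0.0650) or array weights (-1.54, 0.0569). In a fit of only the day 3 groups neither Egfr (0.170) nor Pdgfa (0.127) passed. Adjusted over the list alone 2 rose and 5 fell, and with the block 3 rose and 8 fell (median -0.61, camera adjusted p = 0.0202, and adjusted p = 0.285 with an estimated correlation), and the call was lost with no signal filter (0.0518). The chemokines and inflammation list did not pass at day 1 (adjusted p = 0.236, and 0.00910 with the block) or day 3 (0.0557, and 0.000296 with the block). Of its 19 genes 0 passed at either day, also adjusted over the list alone, while 3 fell at day 1 and 1 rose and 7 fell at day 3 with the block. At day 3 this list also passed with quantile normalization (0.0451) and without replicate 1 (0.0183) or replicate 3 (0.00337).

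The lists of other cell types did not pass at either day. At days 1 and 3 the camera adjusted p was 0.933 and 0.953 for adipocyte, 0.933 and 0.581 for chondrocyte, 0.569 and 0.0557 for skeletal muscle, 0.933 and 0.730 for macrophage and osteoclast, 0.428 and 0.335 for endothelial, 0.933 and 0.218 for epithelial, and 0.983 and 0.170 for neural and glial markers. Single members fell: Cd34, a stem and endothelial cell surface marker, from 255 ± 36.2 to 114 ± 37.2 intensity units at day 1 and from 244 ± 46.7 to 64.4 ± 16.0 at day 3 (SD, n = 3). Pmp22, a myelin protein, fell by 0.99 ± 0.21 and 1.89 ± 0.21 at days 1 and 3. Jup, junction plakoglobin, fell by 2.23 ± 0.34 at day 3, when Tnnc1 also fell. Jup did not pass with the added floor (-0.09, adjusted p = 0.856) or in a fit of only the day 3 groups (0.0933), and with the added floor at day 1 neither Cd34 (0.0593) nor Pmp22 (0.0615) did. With no signal filter and with no mean trend the day 1 calls of Cd34 (0.0641 and 0.0571) and Pmp22 (0.0761 and 0.0694) were lost too, as was that of Pmp22 with median scaling (0.0976). For skeletal muscle the day 3 test passed with the mean of all probe sets (0.0191), with quantile normalization (0.0493) and without replicate 2 (0.0119). A second probe set of Tnnt1, chosen after its values were seen, was at -2.45 ± 0.39 and -4.46 ± 0.39 at days 1 and 3 (adjusted p = 0.0107 and 0.000125), where the one used in the list was at -0.04 and -0.58. A second probe set of Igf1, also chosen after its values were seen, was at -3.40 ± 0.44 at day 3 (adjusted p = 0.00117), where the one used was at -0.67 ± 0.32.

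Of the other lists, the adjusted p at days 1 and 3 was 0.933 and 0.953 for collagen maturation, in which P4ha1 fell, and 0.954 and 0.895 for matrix proteases and inhibitors. It was 0.933 and 0.956 for cell cycle arrest and p53 targets, in which Gadd45b rose at both days and Gadd45g at day 3. The day 3 call of Gadd45b (0.0440) was lost with the added floor (0.0555), no signal filter (0.0746), quantile normalization (0.0533), median scaling (0.0508) and no mean trend (0.0583), and in a fit of only the day 3 groups (0.0739). The list adjusted p was 0.933 and 0.543 for smooth muscle and contractile genes, in which Ccn2 rose at day 3. It was 0.428 at day 1 for osteoclast regulation and paracrine factors, 0.0951 at day 1 for other extracellular matrix, 0.933 and 0.224 for immediate early and serum response, in which Klf10 rose at day 1, 0.933 and 0.529 for endoplasmic reticulum chaperones and stress, and 0.734 and 0.953 for phosphate and mineral handling, in which Alpl rose at day 3. The Wnt pathway list did not pass at day 1 (0.0997, and 0.0475 with the block) or day 3 (0.224, and 0.0206 without replicate 3), and its receptor gene Fzd2 fell by 0.64 ± 0.15 at day 3, a call lost with median scaling (0.204) and in a fit of only the day 3 groups (0.168). A probe set of Wnt4, a gene of that list, was left out by the signal filter. With no filter it rose by 3.72 ± 0.55 and 4.23 ± 0.55 at days 1 and 3, sizes made uncertain by low GP signal. Without replicate 1 or replicate 2 other extracellular matrix passed at day 1 (0.0291 and 0.0459), and without replicate 1 immediate early and serum response passed at day 3 (0.0183). Median, mean and test differed in sign for 9 lists at day 1 and 3 at day 3, all uncalled. At day 1 these were collagen maturation, matrix proteases and inhibitors, cell cycle arrest and p53 targets, adipocyte, chondrocyte, smooth muscle and contractile, endoplasmic reticulum chaperones and stress, phosphate and mineral handling, and endothelial. At day 3 they were collagen maturation, cell cycle arrest and p53 targets, and phosphate and mineral handling.

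The genes that differed at day 1 and day 3 overlapped. Smad6, Enpep, Cmbl, Crabp2, Pdk1, P4ha1 and Aldoa passed at both days in the same direction, with the losses under other settings given above. In all, 14 probe sets were higher at both days, where 0.446 would be shared by independent lists (Fisher's exact test, p = 3.0e-19), and 32 were lower, where 0.977 would be shared (p = 3.0e-44). None, 0, passed in opposite directions, and with the block 251 were shared in direction and 1 was opposite. The days share no arrays, although the replicate numbers pair them, and the single fit gives both days the same spread for each probe set. Probe sets with a small spread can thus pass more readily at both days. The Fisher p-values also treat probe sets as independent, so they only describe the overlap. All 69 day 1 probe sets had the same sign at day 3, and 292 of the 306 day 3 probe sets had the same sign at day 1. Over all tested probe sets the fold changes of the days had r = 0.567 and rho = 0.515, across probe sets, which are not independent replicates. Without replicate 1 or replicate 2, limma called 0 probe sets at day 1, so no overlap could be counted, and r was 0.510 and 0.476. In these fits 485 and 376 probe sets had an unadjusted p under 0.05 at day 1, where chance gives 373. Without replicate 3, 78 were shared and r was 0.477.

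**Figure D3:**
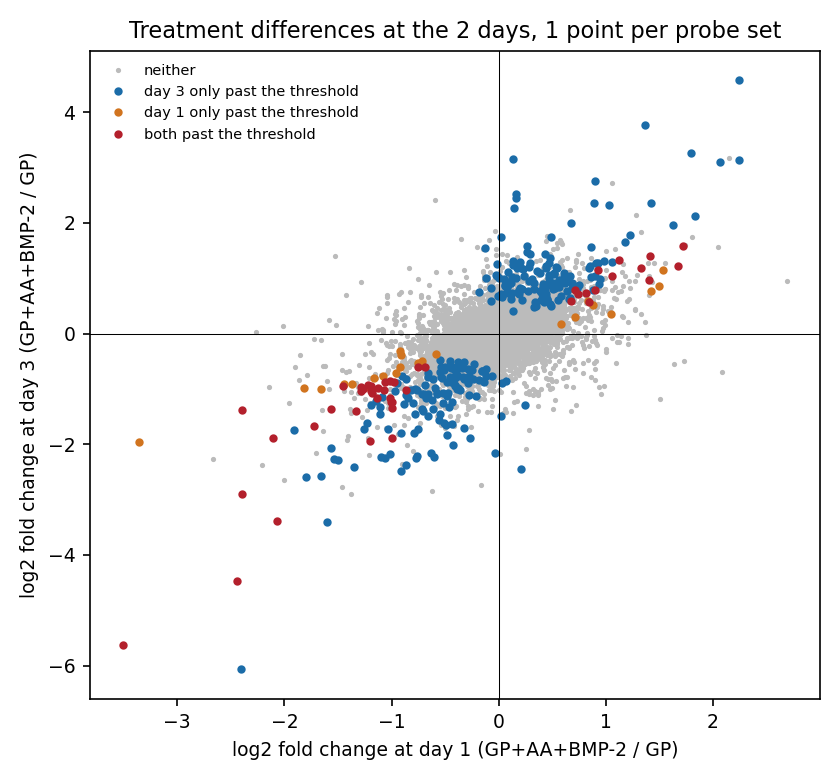
Log2 fold change of treated over GP cultures at day 1 (x axis) against day 3 (y axis), 1 point per tested probe set (7453), coloured by the days at which it passed the threshold. The 46 probe sets past it at both days lie in the quadrants where both changes have the same sign.

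Whether the treatment effect differed between the days was tested with the interaction. Alpl differed by 2.34 ± 0.70 more at day 3 than at day 1, Id3 by 1.46 ± 0.58 more, and Smad7 by -1.12 ± 0.37. Low signal makes the Alpl value uncertain, and with the added floor it was 2.62 (adjusted p = 0.373). None of these passed: limma with Benjamini-Hochberg adjustment called 0 probe sets, the smallest adjusted p was 0.634, and 270 had an unadjusted p under 0.05 where chance gives 373. That fit leaves differences between replicate numbers in its spread, so a count under chance does not show that effects were absent. In the fit that had no block, 1 passed when treated day 1 replicate 3 was left out. With the block 0 passed as well on all arrays, with a smallest adjusted p of 0.0745 in limma and 650 at the unadjusted threshold. With the block and 1 array left out, 15 passed without GP day 3 replicate 3, the array with the high actin ratio, 8 and 3 without treated day 3 replicates 1 and 3, 6 without treated day 1 replicate 3 and 0 without any other array. As a list, cell cycle genes had a median interaction of 0.54 (camera adjusted p = 4.4e-17, and adjusted p = 0.574 with an estimated correlation), with 0 of 51 past the threshold and 7 higher adjusted over the list alone. The osteoclast regulation and paracrine list did not pass (0.206), but did with the block (0.0290) and without replicate 3 (0.0435).

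Between day 0 and GP day 1, proliferation genes rose. Birc5, survivin, rose by 1.57 ± 0.22, Cdc20, an activator of the anaphase-promoting complex, by 1.40 ± 0.16, the proliferation marker Mki67 by 1.39 ± 0.22 and the nuclear import gene Kpna2 by 1.25 ± 0.20 (n = 3 per group). The transcript named D17H6S56E-5 rose by 1.79 ± 0.20. Of 51 cell cycle genes 8 rose, among them Ccnb2 (1.08 ± 0.13) and Cks2 (1.05 ± 0.16), 32 adjusted over the list alone and 21 with the block. Its median was 0.76 and its camera adjusted p 1.0e-58, and the call held with an estimated correlation (adjusted p = 0.0126). Lists that were lower had 0 genes past the threshold, also adjusted over the list alone: smooth muscle and contractile (median -0.29, adjusted p = 3.9e-07, and adjusted p = 0.252 with an estimated correlation), immediate early and serum response (-0.30, 0.00102, and adjusted p = 0.651 with an estimated correlation) and cholesterol synthesis (-0.22, 0.0108, and adjusted p = 0.710 with an estimated correlation). Without replicate 1 the adjusted p was 0.144 for immediate early and serum response and 0.0769 for cholesterol synthesis, and without replicate 2 it was 0.627 for the latter. The cholesterol synthesis median was -0.09 without replicate 2 and -0.40 without replicate 3, and that of immediate early and serum response -0.45 without replicate 3. Collagen maturation did not pass (0.0511, and 0.0253 with the block), and phosphate and mineral handling passed without replicate 3 (0.0387). In limma 18 probe sets rose and 0 fell, with adjusted p = 0.00957 for Birc5 and 0.00240 for Cdc20, and with the block 53 rose and 1 fell. At an unadjusted p under 0.05 limma had 258 probe sets, and 568 with the block, where chance gives 373. With the block, 30 and 28 passed without day 0 replicates 1 and 3 and 27 and 33 without GP day 1 replicates 1 and 2. After median scaling Birc5, Cdc20, Kpna2, Ccnb2 and Cks2 did not pass (adjusted p = 0.0662, 0.0654, 0.237, 0.0898 and 0.173), and in a fit of only these groups none of the genes named here did. Leaving out 1 array gave 4, 6 and 6 probe sets without day 0 replicates 1, 2 and 3 and 3, 6 and 10 without GP day 1 replicates 1, 2 and 3. Of the 5 named genes 3, 2, 3, 2, 3 and 4 passed in these fits, and 2, Cdc20 and D17H6S56E-5, passed in all 6 fits.

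From day 1 to day 3 in GP cultures, the same list went the other way. Both contrasts use the GP day 1 arrays, so a chance value there moves them in opposite directions. Of 51 cell cycle genes 19 fell, 39 adjusted over the list alone and 31 with the block, with a median of -1.03 and a camera adjusted p of 7.2e-58, held with an estimated correlation (adjusted p = 0.0133). Tacc3 fell by 1.93 ± 0.25, Ect2, a regulator of cell division, by 1.68 ± 0.32, Ttk by 1.66 ± 0.31, Cdc20 by 1.54 ± 0.16, and Aurkb and Cks2 both by 1.32 ± 0.16. Cdkn3, a phosphatase of cyclin-dependent kinases, fell by 2.02 ± 0.42 and Id3 by 2.12 ± 0.41. Agt, angiotensinogen, rose by 2.34 ± 0.39 and Htra1, a secreted serine protease, by 1.72 ± 0.31. In limma 53 probe sets passed, 3 higher and 50 lower, with adjusted p = 0.00216 for Tacc3 and 0.0101 for Agt, and with the block 138, 33 higher and 105 lower. The blocked count was 67 and 78 without GP day 1 replicates 1 and 2 and 72 and 76 without GP day 3 replicates 1 and 2. The calls of Id3, Cdkn3, Htra1, Ect2 and Ttk were lost with no signal filter (adjusted p = 0.0863, 0.112, 0.0550, 0.0694 and 0.0550). The first 4 were also lost with the added floor (0.0764, 0.115, 0.0524 and 0.0651) and the last 4 with median scaling (0.149, 0.0716, 0.132 and 0.107). Tacc3 changed by -1.05 with the added floor (0.0156), and in a fit of only these groups neither Tacc3 (0.0604) nor Cdkn3, Htra1, Ect2 or Ttk passed. Leaving out GP day 1 replicates 1 and 2 gave 17 and 29, and leaving out GP day 3 replicates 1 and 2 gave 28 and 17. Of the 7 named genes 1, 1, 3 and 1 stayed past the threshold in these fits, and Tacc3 did so in all 6. Without replicate 3 the adjusted p was 0.0450 for BMP and TGF-beta feedback, 0.00466 for skeletal muscle, 0.0369 for smooth muscle and contractile and 0.000134 for cholesterol synthesis, which did not pass with all arrays (0.328, 0.103, 0.104 and 0.0636).

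GP day 3 cultures were also compared with day 0 cultures. In limma 0 probe sets passed, which does not show that the cultures were alike, with 312 at an unadjusted p under 0.05 where chance gives 373, and with the block 1 passed and 737 were at that level. Leaving out GP day 3 replicate 3, the array with the high actin ratio, gave 1, and 13 with the block, 4 higher and 9 lower. With the block, leaving out day 0 replicate 2 or GP day 3 replicates 1 or 2 gave 0. Cholesterol synthesis was lower as a list (median -0.47, adjusted p = 1.3e-08, and adjusted p = 0.264 with an estimated correlation), as was cell cycle (median -0.13, adjusted p = 6.1e-05, and adjusted p = 0.519 with an estimated correlation), the latter not without replicate 2 (0.206). Without replicates 2 and 3 the medians were -0.20 and -0.88 for cholesterol synthesis and -0.08 and -0.25 for cell cycle. Hypoxia and glycolysis (adjusted p = 0.0235), immediate early and serum response (0.0253), smooth muscle and contractile (0.0325) and BMP and TGF-beta feedback (0.0383) were lower and interferon response was higher (0.0393, and 0.127 with the block). For these 5 the p was the same, adjusted p = 0.519 with an estimated correlation. Collagen maturation tested lower (0.0235, and adjusted p = 0.264 with an estimated correlation) with a mean of -0.17 but a median of 0.01, which was 0.03, -0.05 and -0.06 without replicates 1, 2 and 3. In each of these lists 0 genes passed over all genes, and adjusted over the list alone 1 fell in collagen maturation, 1 fell in smooth muscle and contractile and 0 passed in the others. Without replicates 1 and 2 the adjusted p was 0.0586 and 0.338 for hypoxia and glycolysis, 0.887 and 0.109 for immediate early and serum response, 0.0557 and 0.0531 for smooth muscle and contractile, 0.0557 and 0.0578 for BMP and TGF-beta feedback, 0.358 and 0.238 for interferon response, and 0.119 and 0.119 for collagen maturation. Without replicate 3 it was 0.221 for smooth muscle and contractile and 0.140 for BMP and TGF-beta feedback, while skeletal muscle (0.0397) and endoplasmic reticulum chaperones and stress (0.0473) passed, as they did with the mean of all probe sets (0.0309 and 0.0492). The hypoxia and glycolysis call was lost with quantile normalization (0.0656) and the interferon response call with no signal filter (0.257).

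In treated cultures, some genes differed between day 3 and day 1. Pdgfa rose by 1.64 ± 0.26, Plat, tissue plasminogen activator, by 1.52 ± 0.24, Hdac5, a histone deacetylase, by 0.95 ± 0.16, Bri3 by 0.80 ± 0.14 and the proton pump subunit gene Atp6v1b2 by 0.72 ± 0.13 (n = 3 per group). Ackr3 fell by 2.16 ± 0.32, Nqo1 by 1.85 ± 0.29, Gatm, an enzyme of creatine synthesis, by 1.28 ± 0.19 and Fbln2 by 1.26 ± 0.16. Alpl differed by 2.62 ± 0.50 without passing (adjusted p = 0.0551, and 0.0110 with the block, 0.0260 with the added floor and 0.0161 with array weights). In limma 11 probe sets passed, 7 higher and 4 lower, with adjusted p = 0.00939 for Fbln2 and 0.0205 for Pdgfa, and with the block 286, 151 higher and 135 lower. The blocked count was 136 and 100 without treated day 1 replicates 1 and 2 and 157 without treated day 3 replicate 2. After median scaling 4 were higher and 4 lower, and Pdgfa and Hdac5 did not pass (adjusted p = 0.0581 and 0.110). With the added floor Ackr3 and Nqo1 did not pass (0.0694 and 0.0635), and with quantile normalization Bri3 and Atp6v1b2 did not (0.0586 and 0.0640). With no mean trend Hdac5, Bri3 and Atp6v1b2 did not pass (0.0667, 0.0867 and 0.0971), nor did Atp6v1b2 with robust estimation (0.0502) or median scaling (0.0979). In a fit of only these groups none of the 9 named genes passed. Leaving out treated day 1 replicates 1, 2 and 3 gave 0, 0 and 27, and leaving out treated day 3 replicates 1, 2 and 3 gave 18, 0 and 0. In these fits 0, 0, 8, 7, 0 and 0 of the 9 named genes passed, and none did in all 6. In the fits that gave 0, limma had 439, 529, 576 and 593 probe sets at an unadjusted p under 0.05, where chance gives 373.

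As lists in treated cultures, cell cycle genes were lower at day 3 than at day 1 (median -0.43, camera adjusted p = 2.5e-16, and adjusted p = 0.638 with an estimated correlation), with 0 of 51 past the threshold, 3 lower adjusted over the list alone and 10 lower with the block. BMP and TGF-beta feedback (median -0.21, adjusted p = 0.0279) and epithelial markers (-1.49, 0.0279) were lower and smooth muscle and contractile genes higher (0.28, 0.0255), each with adjusted p = 0.7505 with an estimated correlation and 0 genes past the threshold. Adjusted over the list alone, 1 rose and 2 fell in BMP and TGF-beta feedback, 1 fell among 5 epithelial markers and 0 passed among smooth muscle and contractile genes. The adjusted p was 0.214 for BMP and TGF-beta feedback without replicate 3 (median -0.08, and -0.43 without replicate 2), 0.372 for smooth muscle and contractile without replicate 2 and 0.101 for epithelial without replicate 1. With no signal filter it was 0.130, 0.114 and 0.569 for these lists, with an epithelial median of -0.17, and with quantile normalization 0.0685 for smooth muscle and contractile. Without replicate 3, osteoblast, osteoclast regulation and paracrine, and chemokines and inflammation passed (0.0478 each), and without replicate 1 immediate early and serum response did (0.00250).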

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

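The comparison of the days within preparation numbers was chosen only after its result was seen, the fit without GP day 3 replicate 3 was added after the data were seen but before its own result, and the 4 genes named for low signal were chosen after their values were seen.

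The difference between treated and GP cultures in the cell cycle list was larger at day 3 than at day 1, with a median interaction of 0.538 on the log2 scale (camera adjusted p = 4.4e-17, and adjusted p = 0.574 with an estimated correlation). Over the 9 alternatives run for the lists, the adjusted p from camera or fry ranged from 4.9e-18 to 0.638. RNA quality of the GP day 3 replicate 3 array is argued against as the whole cause of the day 3 difference, since the list's median was 1.03 without that array and 0.85 with it, and so is array scaling, since the median was 0.85 after quantile normalization. Treated minus GP, averaged over the list, was 0.06, 0.32 and 0.58 at day 1 and 0.78, 0.84 and 0.90 at day 3 in replicates 1, 2 and 3, so the day 3 value was higher by 0.52 (SD 0.20, n = 3), with an exact two-sided sign-flip p = 0.25, the smallest that 3 pairs allow. The explanation is left open, and the fall in GP cultures and the day 3 treatment difference share the GP day 3 arrays.

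Probe sets left out by the signal filter also differed between treated and GP cultures when no filter was used: 7 at day 1, of which 5 were higher and 2 lower, and 19 at day 3, of which 15 were higher and 4 lower. The filter took the mean over all arrays, so genes with signal only in treated cultures could be left out of the tests and lists. Wnt4, a Wnt ligand, stood at 70.8 ± 37.5 against 5.07 ± 1.94 at day 1 and 126 ± 80.1 against 5.83 ± 1.37 at day 3 (SD, n = 3). Fabp7, a fatty acid binding protein, stood at 113 ± 26.4 against 8.83 ± 2.75 and 64.4 ± 42.2 against 7.03 ± 5.61. Pth1r, the parathyroid hormone receptor, and Pcp4l1 passed at day 3 and not at day 1. At day 3 Pth1r stood at 203 ± 191 against 6.43 ± 1.99 and Pcp4l1 at 115 ± 61.9 against 2.67 ± 0.84.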

How the results depend on the processing

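The floor at the 50th percentile and the cell cycle list without GP day 3 replicate 3 were chosen only after the data were seen.

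Counts of probe sets past the threshold kept within 1.5 times of the main count for all contrasts with the floors at the 2nd and 25th percentiles, the filter at the 60th percentile, quantile normalization, robust estimation and the minimum fold of 1.5. The floor at the 50th percentile gave 3 for the interaction, 2 for GP day 3 against day 0 and 18 for treated day 3 against day 1. No filter gave 1 for GP day 3 against day 0. Median scaling gave 168 for treatment at day 3, 2 for GP day 1 against day 0 and 25 for GP day 3 against day 1. Without a mean trend 42 passed for treatment at day 1 and 11 for GP day 1 against day 0. Array weights gave 217 and 805 for treatment at days 1 and 3, 44 for GP day 1 against day 0, 139 for GP day 3 against day 1 and 68 for treated day 3 against day 1. Fits of only the groups compared gave 4, 69, 0, 17 and 0 in the same order, with fewer residual degrees of freedom. Where the count was 0, limma had 284 and 536 probe sets at an unadjusted p under 0.05, against 373 by chance. The replicate block gave 372, 1031, 54, 138 and 286 in that order, 1 for GP day 3 against day 0 and an overlap of 251, and apart from the results given beside their main values it changed no other list call and no other call of a named gene reported here. Of the 32 list tests called, 2 were called with an estimated correlation and 9 with fry. Without the block, leaving out an array or a preparation gave 0 to 119 for treatment at day 1, 2 to 503 at day 3, 0 to 1 for the interaction, 0 to 18 for GP day 1 against day 0, 0 to 95 for GP day 3 against day 1, 0 to 8 for GP day 3 against day 0, 0 to 95 for treated day 3 against day 1 and 0 to 78 for the overlap, which had to be 0 where 0 passed at day 1. Where a contrast had 0, limma had 119 to 593 probe sets at an unadjusted p under 0.05, against 373 by chance. With the block, leaving out 1 array gave 105 to 243, 610 to 946, 0 to 15, 27 to 57, 67 to 133, 0 to 13 and 100 to 263 for these contrasts. A group left with 2 arrays shared the spread of the other groups. Except for the smaller fits, the cause was not tested. Of 127 gene results reported, calls were lost for 23 with the floor at the 50th percentile, 21 with no filter, 8 with quantile normalization, 30 with median scaling, 15 without a mean trend, 1 with robust estimation, 1 with array weights and 69 in fits of only the groups compared. Calls were lost for 93, 107 and 12 of them without replicates 1, 2 and 3, where each group kept 2 arrays. The 127 include results that were not called in the main fit and so had no call to lose. The 34, 19 and 105 results unchanged in these 3 fits thus include uncalled ones that stayed uncalled. The sign turned only for 4 reported results, all uncalled: Nog at day 3 was -0.0380 with the floor at the 50th percentile and -0.418 to 0.440 with leave-outs, Nog at day 1 was -0.0187 to 0.220 with leave-outs, Col1a1 at day 1 was 0.0523 with quantile normalization, 0.0556 with array weights and -0.187 to 0.0857 with leave-outs, and Smad7 at day 3 was 0.0330 with median scaling, 0.0734 with array weights and -0.193 to 0.217 with leave-outs. Over all contrasts, 83 of 3635 values of named genes turned sign, none past the threshold. Signal near background limits low probe sets: 12.9% of the values of replicate 3 arrays lay at the floor.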

Other observations

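The tests of a single preparation for hypoxia and glycolysis, of shared class I probes, of macrophage markers and of gene families were chosen only after the results were seen, and the macrophage marker test was set to leave its explanation open after its value was seen.

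The hypoxia and glycolysis list was lower in treated than in GP cultures at both days, with medians of -0.66 and -0.62, but the list call was lost with an estimated correlation (adjusted p = 0.0554 and 0.114). Array scaling is argued against, since the day 1 median was -0.62 after quantile normalization, and so is a single preparation, since the least negative of the 3 day 1 differences was -0.63. A hypothesis that lower activity of hypoxia-inducible factor (HIF) may underlie the pattern was tested, as written before the result, on 41 further HIF targets outside the lists, of which 23 were tested on the arrays. Their median at day 1 was -0.44, below all of 10000 random lists matched on signal, whose 2.5th percentile was -0.19, and 17 of the 23 were negative, with Kdm3a (-1.27) and Fam162a (-1.22), named after their values were seen, past the threshold. This goes with the hypothesis, but the random lists ignore correlation among genes that respond together, so their range may be too narrow. Oxygen was not measured, and an effect of ascorbic acid on the oxygen-sensing hydroxylases cannot be separated here from one of BMP-2.

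The interferon response list was lower in treated cultures at both days with the preset correlation of camera, but not with an estimated correlation (adjusted p = 0.151 and 0.179). At day 3 a single preparation is argued against, since the least negative of the 3 differences was -0.67. At day 1 the differences were -0.28, -0.62 and -0.88 in replicates 1, 2 and 3, so replicate 1 showed less of the pattern. Leaving out the few members with H2- symbols could hardly move a median, so that test cannot decide on probes shared among class I genes. The 17 interferon response genes without H2- symbols had a median of -0.86 at day 3. Fewer macrophage-like cells could lower such genes, and this stays open: the 5 tested macrophage and osteoclast markers had a median of -0.16 at day 3 (SD across markers 0.18), but all except Cd14, at a mean intensity of 602, lay at 34.4 to 57.5, near the array medians.

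Other splits of the arrays were counted for each contrast. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 69 and 0 for treatment at day 1, 306 and 81 at day 3, 18 and 0 for GP day 1 against day 0, 53 and 0 for GP day 3 against day 1, and 11 and 0 for treated day 3 against day 1, each real split being the 1 of 10 with as many. For GP day 3 against day 0 all 10 gave 0, the real count, so they say nothing. The split with 81 put GP day 3 replicates 1 and 2 and treated replicate 2 against the rest and parted 1 pair of replicate numbers, while the other 3 splits that parted all 3 pairs, as the real one does, gave 0. For the interaction the real count was 0, so all 100 of the 100 drawn splits had to give at least as many and the comparison says nothing about chance, while 1 gave 307. The cause of that count is left open.

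Of 171 gene families defined by the stem of their symbols, Mcm, Psmd, Smad, Timm and Cdc were higher at day 1, and Mcm, Cdca, Nup, Cdc, Lsm and Mrpl were higher and Aldh lower at day 3 with the preset correlation of camera. No family passed with an estimated correlation.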
